A study of Oryza sativa with 4 samples.

How the data were processed

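The labels of this series describe 4 poly(A)-selected RNA-seq samples of young panicle from Oryza sativa japonica rice. They give 2 samples of the control, titled Nip, and 2 samples titled osrdr2-3, whose genotype is given as DES1 mutant. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I, enriched on oligo(dT) beads and fragmented, and size-selected cDNA was amplified by PCR. No step that marks the strand is named, so reads from overlapping antisense genes may not be separable. TopHat is named in the submitters' processing notes, without a version. The expression estimator, the genome build and the annotation are not given in the sources used here.

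The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to the number of fragments of the library) that the authors estimated per gene and library, per the file headers. Each row pairs 2 libraries and gives a locus, a test status and the FPKM in both. It gives no read counts, so no count model was fitted, and any scaling between libraries is not stated. Of the 57143 rows for the pair of control libraries, 54168 carried 1 rice locus ID, 1225 carried several IDs and 1750 carried none. Rows without an ID held 1.27% and 1.29% of the summed FPKM. They stayed out of the gene lists and of the random lists.

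The table calls its libraries by short names. The control names with the numbers 1 and 2 were read as Nip replicates 1 and 2, taking the abbreviation ck as control, which the labels do not spell out. Values of 4 further library names in the table were not used. Another control name had no sample in the labels used here. The mutant names carried numbers that do not correspond to replicates 1 and 2, and there were more such names than mutant samples. They were therefore not assigned, and the comparison of osrdr2-3 with the control was not analysed here. All values below come from the 2 Nip libraries. Nothing in the labels says whether these came from separate plants, so their spread may be technical. Whether they differ by more than sampling noise was not tested, since the table gives no counts and no other pair was used.

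Gene symbols do not stand in the table. Lists of genes with their locus IDs were fixed from prior knowledge before the data were examined. Of 162 IDs, 161 were in the table, and 98 had their symbol in a RefSeq gene table of rice (assembly ASM3414082v1) on the same chromosome. A symbol was used only where the RefSeq gene lay within 5 Mb and either its offset differed by at most 250 kb from that of the nearest other listed gene, or its length was within 10% of that of the locus. This left 94 IDs. This rule was set after the table was seen and is stricter than the plan, which kept IDs with no annotation to check. The names therefore rest on prior knowledge of the IDs together with this comparison of positions. The other IDs are not reported, and 13 lists defined by gene descriptions were not used because no descriptions were at hand. Coordinates are those of the deposited table, whose build is not given in the sources used here.

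Before the data were examined, the plan was a limma test between the genotypes. The genes to be named were set as OsRDR2, the measured members of the RNA-directed DNA methylation, methyltransferase and demethylase lists, and, per other list, up to 4 members with the largest fold past the threshold or, where none passed, the 2 most abundant. Genes past the threshold with the largest changes overall were to be added. With 1 group analysed there was no test, so only OsRDR2, those 3 lists and the 2 most abundant members of each other list follow the rule. Further members are named below by a choice made after their values were seen.

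For each gene the mean and SD over the 2 libraries were computed. For values well under 1 FPKM, which can rest on few fragments, this SD is no measure of precision. The authors' test status was NOTEST for 31296 rows and OK for 25846. Of the genes named below, OsAGO7, APO2, LAX1, FZP, FON4, EAT1, TIP2, TDR, PTC1 and HsfA2a had the status NOTEST. A list's level was described by the percentile of its median FPKM among 10000 random lists of the same size, drawn from all rows with 1 locus ID. Of these rows 45.2% were at 0 in both libraries and 62.2% had a mean under 1 FPKM, so a list with a median under 1 FPKM can lie above most random lists. Every list given this percentile below stood at 66.7 or higher, heat shock genes included. A high percentile therefore does not single out a list as one of panicle expression. A list's difference between the libraries was described by the percentile of its median log2(FPKM + 1) difference among 10000 random lists matched on mean FPKM in 20 bins, over rows with a mean of at least 1 FPKM. Both leave out rows with several locus IDs. The level percentile is that of the median of mean FPKM, whereas list medians given per library include rows with several locus IDs. Both need at least 3 genes and describe these libraries only. Both depend on the size of the list, so they do not rank lists of different sizes. The level percentile was added after the data were seen. The difference percentile was tried on simulated counts for 20461 rows. Lists of 20 rows raised and lowered 2-fold lay at the 100th and 0th percentiles, which so large a shift all but fixes. The 40 unchanged lists, drawn from all rows including the shifted ones, had a median percentile of 58.3. The lists reported below had at most 18 rows and median log2 differences of at most 0.123. The simulation therefore does not show how the percentile behaves for them. The depth estimate was tested on 54168 rows simulated as unspliced, which cannot show the error that introns bring to the real estimate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

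The files give no depth. Where few fragments were counted, the ratio of the libraries' values took discrete steps, and its most common step put 1.07 times as many fragments in replicate 1 as in replicate 2. This holds if no further scaling was applied. The low edge of FPKM times locus span, over loci of 1500 to 5000 bp, gave about 42.5 and 44.6 FPKM-bp per fragment. By that estimate 1 FPKM in a transcript of 1 kb rests on about 23.5 and 22.4 fragments. Because locus spans include introns, these are rough values, and no counting intervals were derived from them. Alternatives tried were another pseudocount, other minimum levels, median-ratio scaling, a stricter pairing of symbols and each library alone.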

Results

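Expression was measured by poly(A)-selected RNA-seq in young panicles, the developing inflorescence of rice, in the japonica control line labelled Nip. The study concerns OsRDR2, an RNA-dependent RNA polymerase of the RNA-directed DNA methylation pathway, and its osrdr2-3 mutant. The 2 Nip libraries are described here (n = 2 for every mean ± SD), and the mutant samples were not analysed here. By an approximate estimate, 1 FPKM in a transcript of 1 kb rested on 23.5 fragments in replicate 1 and 22.4 in replicate 2. In all, 22500 rows reached 1 FPKM in replicate 1 and 22346 in replicate 2, with 21839 at or above that level in both. In replicate 1, 26079 rows were listed at 0, against 26192 in replicate 2, and 24586 were at 0 in both. The 10 most abundant rows held 6.9% and 6.38% of the summed FPKM.

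OsRDR2 was expressed in both control libraries. The gene, which makes the double-stranded RNA from which small interfering RNAs are cut, was at 13.78 FPKM in replicate 1 and 12.82 FPKM in replicate 2, a mean of 13.3 ± 0.679 (SD, n = 2). Its locus, LOC_Os04g39160, lies on chromosome 4 from 23284654 to 23290538 as the table gives it, with a build that is not given in the sources used here. The level stood above 82.3% of rows with 1 locus ID. The 2 libraries differed by 0.10 on the log2(FPKM + 1) scale.

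The pathway's effector OsAGO4a, an Argonaute that binds small interfering RNAs, was far more abundant than OsRDR2, and the methyltransferase OsDRM2 lay between them. OsAGO4a (LOC_Os01g16870, chromosome 1, 9631295 to 9638901) was at 171.6 ± 2.13 FPKM. OsDRM2 (LOC_Os03g02010, chromosome 3, 632428 to 636395), the de novo methyltransferase of the pathway, was at 21.97 ± 0.725 FPKM. The order OsAGO4a, OsDRM2, OsRDR2 held in both libraries, and each step exceeded the replicate SDs. These are the 3 of 12 listed pathway members whose symbols could be paired with a locus. Their median stood at the 95.7th percentile of random lists. Here and below these lists were drawn from rows of which 62.2% had a mean under 1 FPKM, so most lists of expressed genes rank high.

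Among maintenance methyltransferases, OsMET1-2 and OsCMT3a exceeded 1 FPKM in both libraries and OsMET1-1 did not. OsMET1-2 (LOC_Os07g08500), which belongs to the family that maintains CG methylation, was at 7.78 ± 0.137 FPKM, and its paralog OsMET1-1 (LOC_Os03g58400) at 0.647 ± 0.125 FPKM. The values were higher for OsMET1-2 in both libraries. How reads shared by these paralogs were assigned is not known. OsCMT3a (LOC_Os10g01570), a chromomethylase of CHG sites, was at 3.77 ± 0.00134 FPKM. The methyltransferase list, with OsDRM2, stood at the 81.5th percentile of random lists. OsROS1c (LOC_Os05g37350), a DNA glycosylase that removes methylated cytosine, was the 1 paired member of the demethylase list and was at 1.97 ± 0.175 FPKM. The OsROS1c row had a long span (chromosome 5, 21839537 to 21896908), so the value may not be of that gene alone.

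Other small RNA genes covered a wide range. OsAGO1b and OsAGO1a, Argonautes of the microRNA pathway, were the most abundant of this list at 103.6 ± 0.0644 and 70.4 ± 0.454 FPKM. OsAGO1d followed at 31.74 ± 0.659 FPKM and OsAGO1c at 25.8 ± 0.183 FPKM. Among Dicer-like genes, OsDCL4 was at 31.6 ± 0.479 FPKM and OsDCL2a at 9.73 ± 0.209 FPKM. OsRDR6, the polymerase of trans-acting small interfering RNA synthesis, was at 5.63 ± 0.0393 FPKM. OsAGO18 was at 13.4 ± 0.620 FPKM, and MEL1, a germ-line Argonaute, at 1.99 ± 0.0434 FPKM. OsAGO7 was the lowest, at 0.138 and 0.0910 FPKM. OsAGO2 and OsAGO3 shared 1 row in the table, at 9.10 ± 0.121 FPKM, and could not be separated. Of the 13 rows of this list, 12 reached 1 FPKM in both libraries and 7 reached 10 FPKM, and the median stood at the 99.4th percentile of random lists.

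Floral organ identity genes were highly expressed. All 19 paired members exceeded 10 FPKM in both libraries, and the list's median of 79.3 and 82.2 FPKM lay at the 100th percentile of random lists. OsMADS1 (LOC_Os03g11614, chromosome 3, 6052749 to 6118762), a SEPALLATA-like gene of lemma, palea and floret meristem fate, was at 1670 ± 21.6 FPKM and ranked 23 among all rows. Its row had the longest span of the list, so the value may not be of that gene alone, which was not checked. The related E-function gene OsMADS8 was at 440.1 ± 6.98 FPKM and OsMADS7 at 295.6 ± 7.05 FPKM. OsMADS15, of the APETALA1/FRUITFULL group, was at 251.5 ± 4.57 FPKM. The stamen and carpel genes OsMADS58 and OsMADS3 were at 162.3 ± 7.35 and 115.1 ± 3.04 FPKM, where the OsMADS58 row also held another locus ID. The ovule gene OsMADS13 was at 116.5 ± 4.11 FPKM, and the lodicule and stamen gene OsMADS16 at 89.9 ± 0.457 FPKM. The lowest members were DL, a carpel and leaf-midrib gene, at 16.9 ± 0.378 FPKM and OsMADS34 at 14.8 ± 0.113 FPKM.

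**Figure D1:**
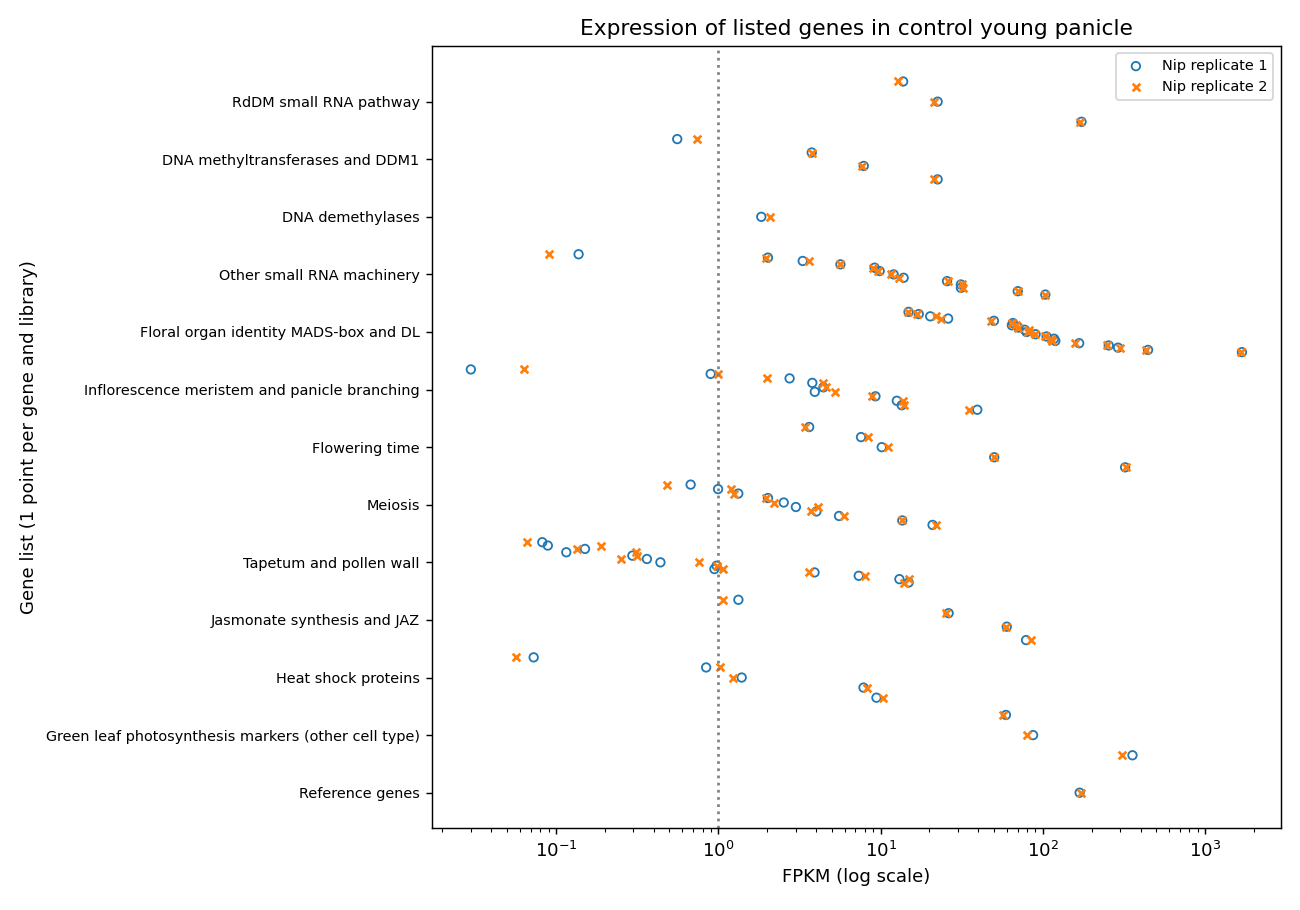
FPKM (log axis) of each paired gene in the 2 Nip libraries, arranged by gene list, with circles for replicate 1, crosses for replicate 2 and a dotted line at 1 FPKM. 4 genes with a value of 0 in a library are left out; all 19 floral identity genes lie above 10 FPKM, whereas 4 of 13 tapetum and pollen wall genes reach 1 FPKM in both libraries.

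Genes of inflorescence meristems and branching covered a wide range. The homeobox gene OSH15 was at 37.4 ± 2.96 FPKM, OsMADS22 at 13.75 ± 0.334 FPKM and the KNOX gene OSH1 at 13.2 ± 0.863 FPKM. FON1, a receptor kinase that limits floral meristem size, was at 9.09 ± 0.302 FPKM. IPA1 was at 2.75 and 2.00 FPKM. LAX1 of axillary meristems, FZP of spikelet meristem fate and FON4, the CLAVATA3-like peptide gene, were listed at 0 in both libraries, and APO2 was at 0.0299 and 0.0639 FPKM. In all, 8 of 13 paired members reached 1 FPKM in both libraries, and the list's median stood at the 95th percentile of random lists.

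Among flowering time genes, the circadian gene OsGI was at 322.4 ± 1.46 FPKM and OsMADS56 at 50.2 ± 0.0351 FPKM. Hd1 was at 10.6 ± 0.618 FPKM and the florigen Hd3a at 7.58 FPKM in replicate 1 and 8.42 FPKM in replicate 2. The list's median stood at the 94.3rd percentile of random lists.

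Of 10 paired meiosis genes, 8 reached 1 FPKM in both libraries, and the list's median stood at the 86.7th percentile of random lists. PAIR2, a HORMA-domain protein of the chromosome axis, was at 21.5 ± 0.819 FPKM, and the crossover helicase MER3, on a row with another locus ID, at 13.6 ± 0.0179 FPKM. OsSPO11-1, which makes meiotic double-strand breaks, was at 5.75 ± 0.287 FPKM, OsDMC1A at 3.88 ± 0.204 FPKM and HEI10 at 3.56 ± 0.775 FPKM. ZEP1, of the synaptonemal complex, was at 1.29 ± 0.0576 FPKM. The ZEP1 row had a very long span (chromosome 4, 22562483 to 22791327), so the value may not be of that gene alone. PAIR1 was the lowest at 0.578 ± 0.138 FPKM. OsDMC1A has a near-identical copy, so its value is uncertain.

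Of 13 paired tapetum and pollen wall genes, 4 reached 1 FPKM in both libraries. The list's median was 0.44 FPKM in replicate 1 and 0.762 FPKM in replicate 2. By mean FPKM, the median of its members with 1 locus ID stood at the 66.7th percentile of random lists. These were drawn from rows of which 62.2% had a mean under 1 FPKM. OsAP25, an aspartic protease gene of the tapetum, at 14.4 ± 0.661 FPKM and GAMYB, a gibberellin-response transcription factor, at 14.0 ± 1.37 FPKM were the most abundant. MSP1, a receptor kinase that limits sporocyte number, was at 7.70 ± 0.514 FPKM and RTS at 3.78 ± 0.202 FPKM. The tapetal bHLH genes UDT1, EAT1, TIP2 and TDR were at 1.01 ± 0.0852, 0.308 ± 0.0793, 0.306 ± 0.0142 and 0.213 ± 0.137 FPKM. The lipid and exine genes CYP703A3, on a shared row, and OsC6 were at 0.979 ± 0.00252 and 0.601 ± 0.227 FPKM. PTC1, a PHD-finger regulator of late tapetum development, was at 0.0742 ± 0.0116 FPKM. EAT1, TIP2, TDR and PTC1 had the authors' status NOTEST.

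Photosynthesis genes, fixed as markers of green tissue, were abundant. The chlorophyll a/b-binding protein gene CAB2R was at 331.8 ± 35.1 FPKM, CAB1R at 83.5 ± 5.08 FPKM and 1 paired RBCS gene (LOC_Os12g17600) at 58.2 ± 1.45 FPKM, and the median of these 3 of 7 listed genes stood at the 99.8th percentile of random lists. These genes belong to families with similar copies, so their values are uncertain. Each value was higher in replicate 1, by 0.22, 0.12 and 0.05 on the log2 scale. The median difference of 0.12 lay at the 98.5th percentile of level-matched random lists. The floral identity list lay at 94.6, from 18 of its 19 paired genes, and the tapetum list at 8.5, from 5 of its 13. The 11 lists with such a percentile ranged from 8.5 to 98.5, each over its members with 1 locus ID and a mean of at least 1 FPKM. The photosynthesis value is thus the highest of 11, which lessens its weight. Random lists draw unrelated rows, whereas genes of a list may vary together, so these percentiles can overstate how unusual a difference is.

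Of the jasmonate genes, EG2/OsJAZ1, a jasmonate-signalling repressor, was at 81.6 ± 3.96 FPKM and the synthesis gene OsOPR7 at 59.7 ± 0.363 FPKM. OsAOC was at 25.75 ± 0.727 FPKM and OsAOS2 at 1.20 ± 0.187 FPKM. The median of these 4 of 10 listed genes stood at the 99.4th percentile of random lists. Of the heat shock genes, HSP17.9 was at 9.93 ± 0.695 FPKM, HsfA2c at 8.07 ± 0.314 FPKM and HSP101 at 1.31 ± 0.115 FPKM. HSP18.6 was at 0.933 ± 0.129 FPKM and HsfA2a, with the authors' status NOTEST, at 0.0648 ± 0.0114 FPKM. The median of these 5 of 13 listed genes stood at the 75.9th percentile. The reference gene ACT1 was at 170.5 ± 2.66 FPKM. No mature pollen marker of the fixed list could be paired with its symbol, so none is reported.

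Across the 22443 rows with a mean of at least 1 FPKM, log2(FPKM + 1) of the 2 libraries correlated with Pearson's r = 0.989 and Spearman's rho = 0.99. This correlation is across genes, which are not independent replicates. The median log2 difference was 0.004, and 176 rows (0.784%) differed at least 2-fold on the pseudocount scale. Of these, 123 were higher in replicate 1 and 53 in replicate 2. The spread between libraries fell with the level, from a robust SD of 0.371 on the log2 scale at 1 to 2 FPKM (95% bootstrap interval 0.356 to 0.391) to 0.055 at 100 to 1000 FPKM (0.051 to 0.059).

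**Figure D2:**
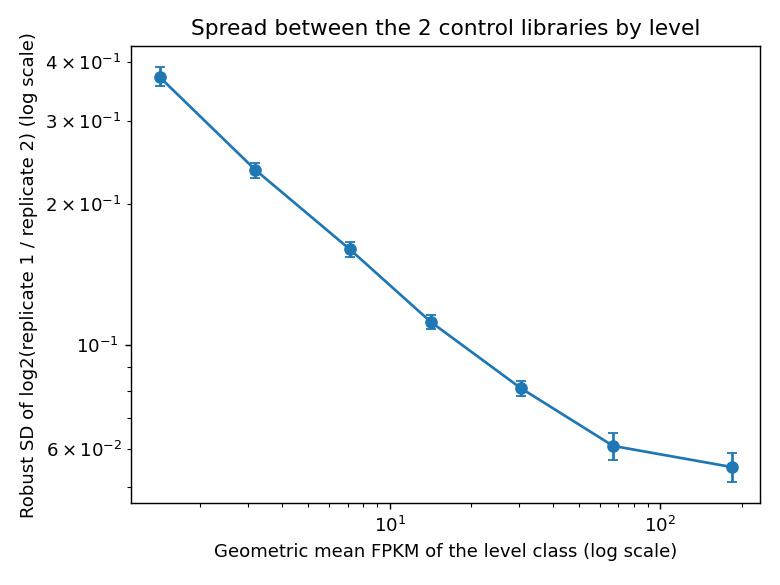
Robust SD of the log2 ratio of replicate 1 to replicate 2 (log axis) against the geometric mean FPKM of 7 level classes (log axis), for rows above 0 in both Nip libraries. Points are classes and bars 95% bootstrap intervals over rows; the spread falls from 0.371 at 1 to 2 FPKM to 0.081 at 20 to 50 FPKM and to 0.055 at 100 to 1000 FPKM.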

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

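For the count of listed genes, the minimum levels of 5 and 0.5 FPKM and the pairing of symbols by locus length alone were chosen after the data were seen. The mean level of OsRDR2 was 13.3 FPKM with the deposited values and 13.32 FPKM after median-ratio scaling, and the single libraries gave 12.82 to 13.78 FPKM. With 2 libraries neither setting tests stability, because each library lies within 1 SD of the mean by construction and the median ratio of the libraries was 1.0. Of the rows of paired listed genes, 72 reached 1 FPKM in both libraries. Each library alone gave 72 to 75, median-ratio scaling 72, a minimum of 5 FPKM 56, a minimum of 0.5 FPKM 78, and pairing by length alone 56. The correlation between the libraries was 0.989, also with a mean of at least 5 FPKM and with median-ratio scaling. It was 0.996 with no filter on low values and 0.976 with a pseudocount of 0.1. Without the filter, the 24586 rows at 0 in both libraries enter as identical points. A smaller pseudocount widens the log2 difference of rows at 0 in 1 library. How much of either change these rows account for was not tested. The percentiles of the list differences stayed on the same side of the outer 2.5% in 32 of 33 settings. These include median-ratio scaling for each list, which could hardly move a percentile with a median ratio of 1.0. For the same reason that scaling does not test the correlation or the count of listed genes. Without the filter on low values, the inflorescence meristem list went from 13.8 to 1.6. Some lists moved without crossing the outer 2.5%. Without that filter the flowering time list went from 10.5 to 41.3, and the meiosis list from 26.5 to above the middle of the random lists. With a pseudocount of 0.1 the tapetum list went from 8.5 to 3.8. The causes were not tested. No paired analysis was possible because values of 1 group alone were used. For the same reason the planned test between genotypes, its replicate block, thresholds, trend setting, list tests and transposon lists were not run, and neither were other pseudocounts for OsRDR2 or single genes, whose levels use none. At 1 to 2 FPKM the spread between libraries was 0.371 on the log2 scale, and how much of it comes from depth was not separated from other sources.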

Other observations

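All tests in this part were chosen after the values were seen. The most abundant row of both libraries was LOC_Os08g08960 (chromosome 8, 5208384 to 5209569), at 13641.3 and 13792.8 FPKM. The next, LOC_Os04g02670 (chromosome 4, 1008360 to 1010071), was at 12640.7 FPKM in replicate 1 and 7416.76 FPKM in replicate 2, an uneven pair for so abundant a row. Gaps between the libraries were ranked on the log2(FPKM + 1) scale, among rows with 1 locus ID and a mean of at least 1 FPKM. The largest was that of LOC_Os04g42050, at 51.9 FPKM in replicate 1 and listed at 0 in replicate 2. Its span was 502 bp, just over the limit of 500 bp used below for short loci. The largest gap the other way was that of LOC_Os12g11610, listed at 0 in replicate 1 and at 25.98 FPKM in replicate 2. That row spanned 353339 bp, so shortness does not account for it. The table gives no names for these IDs.

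The spread between the libraries fell as the level rose. Counting noise is a candidate explanation at 1 to 50 FPKM. It requires the log spread to fall with a slope of -0.5 on the log level if transcript length is unrelated to level, which was not checked. The fitted slope over 5 level classes was -0.498 (95% bootstrap interval over rows -0.515 to -0.483). It used rows above 0 in both libraries only, which can narrow the spread in the lowest classes. Counting noise is thus not excluded, but it stays open, since 1 pair of single libraries cannot separate it from other sources of spread. Above 50 FPKM the spread fell more slowly, to 0.061 at 50 to 100 FPKM and 0.055 at 100 to 1000 FPKM, and how much of that comes from transcript length, plants or library preparation was not tested.

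In 32 rows a library was listed at 0 while the other was at 5 FPKM or more. Short loci may be over-represented among them. Of the 32 rows, 21 (65.6%) spanned 500 bp or less, against 99 of 12687 rows above 0 in both libraries within the same range of mean FPKM (0.78%; two-sided Fisher's exact test, p = 5.5e-36, rows not being independent replicates). The test shows only that the spans are short. At a short locus few fragments give a high FPKM, so choosing rows by 0 against 5 FPKM or more favours short spans in advance. The p-value therefore lends no weight to a cause. Fragments were not counted directly. By the rough depth estimate, with the span taken as the length, the lowest value among the short rows corresponds to 25.3 fragments, with a median of 40.2. These are not lower bounds. Fewer fragments would give the same FPKM if the length used by the estimator was shorter than the span. Few fragments in these rows are therefore not excluded. Why the other library was at 0 stays unexplained for the short and the longer rows. No biological explanation was tested because both libraries belong to 1 group.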
